A study of Mus musculus with 33 samples.

How the data were processed

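RNA of bone marrow-derived macrophages (BMDM) and primary embryonic fibroblasts (MEF) was measured on 33 Illumina MouseRef-8 bead arrays, 23 for BMDM and 10 for MEF. Per the labels, BMDM were grown in L929-conditioned medium for 5 to 8 days, MEF were used at passages 5 to 6 in medium with 10% serum, and biotin-labelled cRNA was hybridised. Samples were grouped by cell type, genotype, agent and time as the labels give them, into 31 groups. WT unstimulated replicate 1 of BMDM is the array labelled with the CpG series and replicate 2 that of the LPS series; in MEF replicate 1 belongs to the LPS series and replicate 2 to the IFNb series. The single unstimulated p50KO BMDM array belongs to the CpG series.

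The values used were the bead intensity of each probe on a linear scale, which the authors deposited without normalization, and the detection p-value of each probe against the array's negative controls, deposited by the authors beside each intensity. Per the file headers the detection p-value stands to the right of its intensity, and it fell as the intensity rose on every array. The authors used BeadStudio, per the submitters' processing notes, with no version given. A second deposited set of intensity values had been normalized by the authors on a linear scale, and the method is not given in the sources used here. It ranked the probes of each array as the unnormalized values did, and its medians were 62 to 62.2 in the CpG series, 55.3 to 57.1 on the other BMDM arrays and 64.2 to 66.5 in MEF. It served only as an alternative. In the BMDM file 8 lines held no values, and 14 MEF probes were in the unnormalized values alone; no other column of values per sample was left unused (0).

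Background was corrected with the normexp method of limma's nec, with negative controls taken from the detection p-values and an offset of 16, and arrays were quantile normalized and put on log2, separately for BMDM (25697 probes) and MEF (24599 probes). Gene symbols came from the platform annotation, updated through a gene table of assembly GRCm38.p6. In BMDM 23978 probes had 1 symbol, 0 several and 1719 none, and 23962 matched that table; in MEF these were 20974, 1, 3624 and 20958. Probes with several symbols or none were not named. Genes were tested where a probe had a detection p under 0.01 on at least 2 arrays of the cell type, 9154 in BMDM and 9099 in MEF, and a gene with several probes was given by its brightest. With the mean of its detected probes instead, no named gene reversed its direction. Software was R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

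All gene tests were two-sided limma tests (lmFit and eBayes) with Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. Errors are standard errors of the fit unless a sentence says otherwise. Because each condition had 1 array per genotype, the p50 difference was tested as the mean over 10 matched BMDM conditions (21 arrays, condition as a factor) and over 4 matched MEF conditions, and by stimulus as the mean over 1, 3 and 8 h, with the spread between conditions as its error. An effect that changes with time therefore adds to that error. Responses to the agents were tested over both genotypes with genotype as a term. IFNARKO arrays, the induction of each genotype and IFNb in MEF had 1 array and no test; they are given as log2 differences and counts at 2-fold, and lists as medians, with percentiles among 10000 random lists matched on mean expression. Genes were called dependent on the interferon receptor where LPS at 3 h induced them at least 2-fold in WT and the induction was at least 2-fold lower in IFNARKO, and independent where it was lower by less than 1.5-fold. A gene not well above background on any array of a group is given as at least N-fold: the mean of the brighter group over the mean, per array, of the higher of the gene's own value and the lowest value among probes above background. Levels are normalized log2 intensities.

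The design, the alternatives, 20 gene lists with 294 genes and the rule for named genes were fixed before the data were examined. The lists were type I interferons, type I interferon antiviral effectors, interferon-inducible GTPases, interferon pathway and interferon regulatory factors, MHC class I presentation, NF-kB subunits and inhibitors, inflammatory cytokines and enzymes, chemokines, immediate-early genes, TLR signalling components, alternative activation, cell cycle, heat shock and stress, genes near the disrupted p50 locus, and markers of macrophages, dendritic cells and MHC class II, granulocytes and progenitors, lymphocytes, erythroid and mast cells, and fibroblasts. A list with at least 3 measured members was tested in BMDM by an exact two-sided sign-flip permutation of its mean difference over the conditions, and by limma's camera with a preset correlation of 0.01 and with an estimated one; other lists are given by gene. Named genes were the 10 largest rises and 10 largest falls among called genes that moved the same way in at least 8 of 10 BMDM conditions, in all 4 MEF conditions, at all 3 times of a stimulus, or in both genotypes for a response. For comparisons without a test they were the 10 largest each way among genes detected in the higher sample. The 4 members of each list with the largest change, and a set of well-known cytokine and interferon genes, could be named too. Genes on chromosome 3 and genes lost or added under an alternative were named after their values were seen.

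The tests were run on simulated data with 200 changed genes. The simulated noise was independent between arrays, and each changed gene had the same effect in every condition. Array series, shared cultures and effects that change with time were not simulated, so the real error may be larger. For the p50 difference over BMDM conditions (9154 genes) 96 of 100 genes changed by 1 log2 and 100 of 100 changed by 2 log2 were recovered, with 8 false calls. For CpG these were 69 and 99 with 10 false calls, for LPS 65 and 99 with 15, for IFNb 67 and 99 with 13, and over MEF conditions (9099 genes) 72 and 94 with 6. The number of arrays limits the precision of every value.

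Alternatives were quantile normalization without background correction, scaling to the 75th percentile, the authors' normalized values, no detection filter or a stricter one, the mean of a gene's probes, a trended and robust spread, leaving out conditions, times or either unstimulated WT array, no condition term, and 3-fold classes. Added after seeing the data were the array series as a block (a random block in MEF, by duplicateCorrelation, where the p50KO arrays were set apart by their number of probes above background and not by a label), each BMDM series alone, fits without the LPS arrays or without the p50KO LPS arrays, the baseline of the same series, and the GTPases without Gbp2b. The genes of p50 and some other members of the lists were not analysed here. The files name no chip, so no block by chip was fitted.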

Results

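Gene expression was measured on 33 single-colour bead arrays of mouse cells, all labelled C57BL/6. Of these, 23 held RNA of bone marrow-derived macrophages (BMDM) and 10 held RNA of primary embryonic fibroblasts (MEF). The macrophages were wild type (WT, 11 arrays), lacked the NF-kB subunit p50 (p50KO, 10 arrays) or lacked the receptor of the type I interferons (IFNARKO, 2 arrays). WT and p50KO macrophages were left unstimulated or were given lipopolysaccharide (LPS, a bacterial cell wall component), CpG DNA (a mimic of microbial DNA) or interferon beta (IFNb) for 1, 3 or 8 h. IFNARKO macrophages were left unstimulated or were given LPS for 3 h. WT (6 arrays) and p50KO (4 arrays) fibroblasts were left unstimulated or were given LPS for 1, 3 or 8 h, and WT fibroblasts were also given IFNb for 8 h. Each condition had 1 array per genotype, except the unstimulated WT cells of each type, which had 2. The comparisons ask, after the title of the series, whether p50 holds back genes of the interferon response, and in which stimulus.

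The summed signal of a BMDM array lay between 7430000 and 15020000 intensity units, and 10456 to 12273 probes (40.7 to 47.8%) were above background. The 8 WT and p50KO arrays of the CpG series, with their own unstimulated arrays, had 13100000 to 15020000 units, against 7430000 to 12450000 on the 13 arrays of the LPS and IFNb series. Between the unstimulated WT arrays of these series, 361 genes were at least 2-fold higher and 196 at least 2-fold lower in the CpG series. In MEF, 8266 to 8959 probes were above background on the WT arrays of the LPS series, 10038 and 10089 on the pair of WT arrays of the IFNb series and 11735 to 12389 on the p50KO arrays. The labels do not say that arrays came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

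Over the 10 matched macrophage conditions, 19 genes were higher and 23 lower in p50KO than in WT cells, of 9154 tested (two-sided limma test, adjusted p under the threshold; 1405 genes at an unadjusted p under 0.05). The gene that encodes p50 was not analysed here, so the genotype labels were not checked against it. Gbp2b, an interferon-inducible GTPase, differed most: it was above background on 10 of 10 p50KO arrays and on 0 of 11 WT arrays, at least 94.5-fold higher in p50KO (log2 difference 7.22 ± 0.57, SE, adjusted p = 1.32e-05). Gpr84, a receptor of medium-chain fatty acids (1.33 ± 0.12, adjusted p = 2.47e-05), and Gdf3, a growth factor of the TGF-beta family (1.32 ± 0.11, adjusted p = 2.24e-05), were also higher. So were Saa3, an acute-phase protein (1.88 ± 0.38), Csprs (1.36 ± 0.27), Trim36 (1.05 ± 0.20) and Marcksl1 (0.99 ± 0.13). Further higher genes were the collagenase gene Mmp13 (0.94 ± 0.15), the C-type lectin receptor gene Clec4e (0.82 ± 0.14) and Ifitm1, an interferon-induced membrane protein (0.80 ± 0.15). Their adjusted p ran from 0.00127 for Marcksl1 to 0.0467 for Saa3. The lower genes were led by Eif4e, which encodes the cap-binding protein of translation (-1.73 ± 0.09, adjusted p = 1.02e-07), Mcoln3, an endolysosomal channel (-1.63 ± 0.14, adjusted p = 2.41e-05), and Ebi3, a subunit of interleukin 27 (-1.52 ± 0.20, adjusted p = 0.00144). Hscb, a cochaperone of iron-sulfur cluster assembly, was above background on 0 of 10 p50KO arrays and was at least 1.79-fold lower (-1.34 ± 0.11, adjusted p = 1.32e-05). Bgn, a proteoglycan (-1.25 ± 0.23), Abcd3, a peroxisomal transporter (-1.11 ± 0.11), Epb41l3 (-1.10 ± 0.19), Slc6a13 (-0.95 ± 0.19), Adcy2 (-0.93 ± 0.14) and the lysosomal enzyme gene Idua (-0.89 ± 0.09) were lower too. Their adjusted p ran from 5.15e-05 for Abcd3 and Idua to 0.0457 for Slc6a13. Of the 42 genes, 8 lie on chromosome 3, the chromosome of the disrupted gene: Abcd3, Ctsk, Eif4e, Gbp2b, Gclm, Gstcd, Mcoln3 and Pla2g12a. For these, an effect of p50 cannot be told apart from a stretch of chromosome linked to the disrupted gene.

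With the array series as a block, 16 genes were higher and 28 lower, and Saa3 (adjusted p = 0.0674) and Csprs (adjusted p = 0.0634) missed the threshold. Each stimulated condition lies in 1 series, so that block is set by 1 array, the unstimulated WT array of the LPS series. For the p50 difference the block equals leaving that array out and is no separate check. Within the CpG series alone 316 genes were higher and 279 lower, and within the LPS and IFNb series alone 4 were higher and 11 lower. Without the CpG arrays 10 genes passed, without the 1, 3 or 8 h arrays 11, 12 or 15, and without the unstimulated arrays 25. Without the LPS arrays 14 were higher and 21 lower, and Saa3, Trim36, Clec4e, Ifitm1, Bgn and Slc6a13 missed the threshold.

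**Figure D1:**
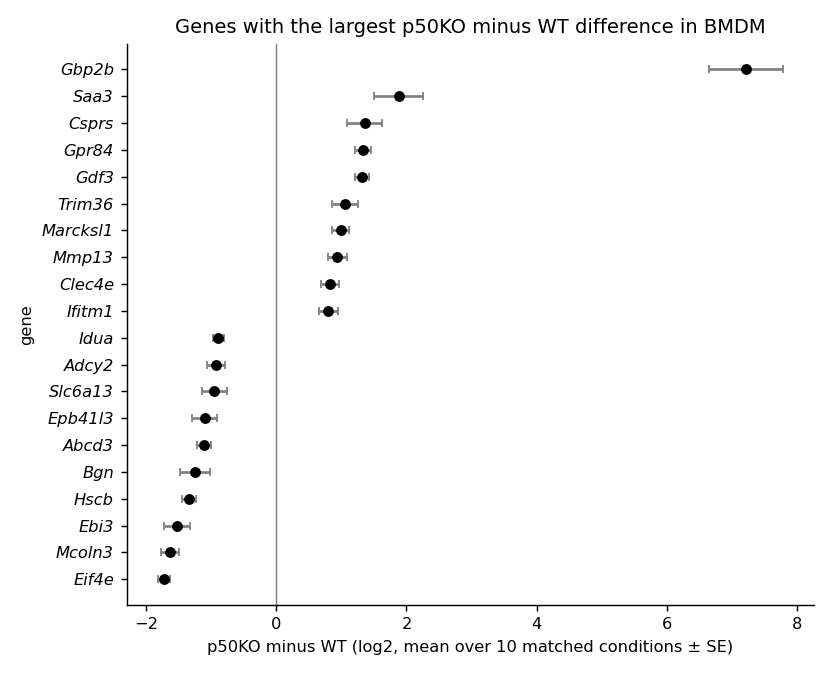
Log2 difference between p50KO and WT macrophages for the genes with the largest differences, as the mean over 10 matched conditions with its standard error from limma. Gbp2b, at 7.22, lies far above the other higher genes, which reach 1.88, and Eif4e, at -1.73, is the lowest.

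Among the interferon lists, the effectors and the GTPases lay higher in p50KO macrophages by the sign-flip test, but not by camera with an estimated correlation. The type I interferon antiviral effectors (28 measured) were higher by a mean of 0.83 log2 (SD 1.0 over 10 conditions) and were higher in 10 of 10 conditions. The exact two-sided sign-flip p = 0.00195 was the smallest these conditions can give (adjusted p = 0.0104). In limma 0 of these genes passed over all genes and 20 when adjusted over the list alone. Oasl1 (1.96), Mx1 (1.41), Ifit3 (1.40) and Cmpk2 (1.31) had the largest differences. The interferon-inducible GTPases (11 measured), which act against intracellular pathogens, were higher by 1.39 (SD 1.1) and in 10 of 10 conditions (adjusted p = 0.0104). Among them 1 passed over all genes and 6 when adjusted over the list alone, with Gbp2b ahead of Gbp3 (1.23), Gbp5 (1.13) and Gbp7 (1.09). Without Gbp2b their mean was 0.80 (SD 1.12), higher in 8 of 10 conditions (exact sign-flip p = 0.0156). The dendritic cell and MHC class II markers (8 measured) were higher by 0.30 (SD 0.28) in 10 of 10 conditions (adjusted p = 0.0104), with 0 genes passing over all genes and 4 when adjusted over the list alone. Ciita, the master regulator of MHC class II (0.58), H2-DMa (0.55), H2-Ab1 (0.42) and Cd74 (0.35) had the largest differences. limma's camera test with a preset correlation of 0.01 gave adjusted p = 5.46e-16, 2.21e-08 and 0.000121 for these 3 lists, but adjusted p = 0.245, 0.218 and 0.218 with an estimated correlation. Without the LPS arrays their means were 0.58, 1.06 and 0.22, higher in 7 of 7 conditions for each, and missed the threshold (adjusted p = 0.05 for all 3), with the smallest exact p that 7 conditions can give (0.0156). Within the LPS and IFNb series alone the means were 0.8, 1.37 and 0.31 and missed the threshold. Between the unstimulated arrays of the CpG series the effectors differed by 0.17, against 0.87 with both WT arrays as the baseline.

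The other lists did not pass the exact sign-flip test. The interferon pathway and interferon regulatory factors (14 measured) had a mean of 0.28 (adjusted p = 0.075) and 1 gene when adjusted over the list alone, with Irf7 (1.12), Stat2 (0.71) and Irf1 (0.67) as the largest. TLR signalling components (14 measured) had 0.22 (adjusted p = 0.075; 3 genes over the list alone; Tlr3 0.65). MHC class I presentation (15 measured) had 0.29 (4 genes over the list alone; Tap2 0.58, Tap1 0.55) and the chemokines (15 measured) 0.31 (3 genes; Cxcl2 1.01, Cxcl9 0.84, Cxcl10 0.82). The inflammatory cytokines and enzymes (15 measured) had 0.26 (0 genes; Il27 0.90, Ptges 0.86) and alternative activation (4 measured) 0.27. The macrophage markers (8 measured) had 0.08 (1 gene; Fcgr1 0.96) and heat shock and stress (8 measured) 0.24 (1 gene; Hspa1a 1.09). For these 6 lists the adjusted p was 0.211. NF-kB subunits and inhibitors (13 measured) had a mean of 0.04 (adjusted p = 0.76), with 2 genes higher and 1 lower over the list alone, and Nfkbiz at 0.57 beside Nfkb2 at -0.46. The immediate-early genes (14 measured) had -0.19 (adjusted p = 0.523; 1 gene lower over the list alone; Fos -0.64), granulocyte and progenitor markers (11 measured) -0.16 and the cell cycle list (13 measured) -0.23 (adjusted p = 0.458 for both). Genes near the disrupted p50 locus (14 measured) had a mean of -0.10 (adjusted p = 0.211), with 1 lower over all genes and 3 higher and 3 lower over the list alone. With the preset correlation camera also called the interferon pathway (adjusted p = 0.00263), MHC class I (3.85e-05), the TLR components (0.00125), the chemokines (0.00737), the inflammatory list (0.0186), alternative activation (0.026) and the cell cycle (0.0449). With an estimated correlation it called none (smallest adjusted p = 0.218). Lists with under 3 measured members gave single genes that did not pass: Ifnb1 (0.27 ± 0.23) and Ifna6 (0.00 ± 0.08) for the type I interferons and Cd79b (0.07 ± 0.14) for lymphocytes. Fcer1a (0.01 ± 0.09) stood for erythroid and mast cells, and Col1a2 (-0.11 ± 0.08) and Vim (-0.01 ± 0.09) for fibroblasts.

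**Figure D2:**
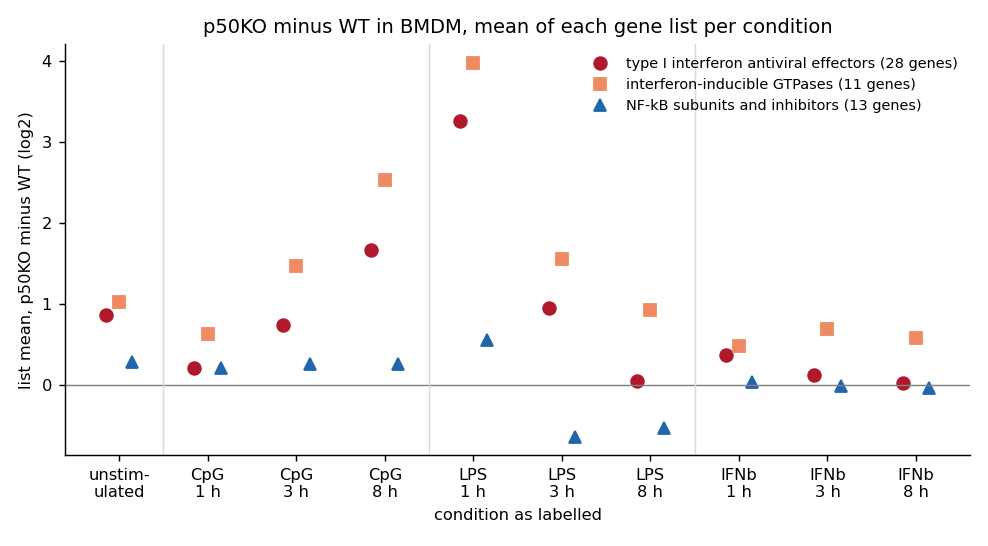
Mean log2 difference between p50KO and WT macrophages for 3 gene lists in each of 10 conditions, 1 point per list and condition. The antiviral effectors lie at 0.22 at CpG 1 h and 1.67 at CpG 8 h, lie at 3.26 in the arrays labelled LPS 1 h and stay between 0.03 and 0.38 with IFNb.

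With CpG, 21 genes were higher and 8 lower in p50KO than in WT macrophages over the 3 times (479 at an unadjusted p under 0.05). Besides Gbp2b (6.42 ± 0.73, adjusted p = 0.00295, at least 44.5-fold), the interferon-inducible gene Ifi202b (5.02 ± 0.59, adjusted p = 0.00373) was higher and not well above background on any WT array of the contrast, at least 27-fold. The neutrophil chemokine gene Cxcl1 (3.74 ± 0.39, adjusted p = 0.00225) and the fatty acid desaturase gene Scd1 (2.19 ± 0.25) were also higher. Trim36 (1.68 ± 0.22), Gpr84 (1.55 ± 0.19), Mmp13 (1.5 ± 0.18), Klk1b11 (1.43 ± 0.19), Tal2 (1.40 ± 0.24) and Ccl6 (1.33 ± 0.23) followed, with adjusted p from 0.00295 for Scd1 to 0.0362 for Ccl6. Npy, which encodes neuropeptide Y, was not well above background in p50KO and at least 106-fold lower (-7.56 ± 0.39, adjusted p = 3.72e-06). Fkbp9 (-2.35 ± 0.23), Id1 (-2.08 ± 0.27), Eif4e (-1.64 ± 0.18), Sdc2 (-1.29 ± 0.21), Hscb (-1.27 ± 0.22), Gclm, a subunit of the glutathione-making ligase (-1.23 ± 0.16), and the serotonin receptor gene Htr2b (-1.11 ± 0.18) were lower. Of the antiviral effectors 27 of 28 had a positive difference and their mean was 0.88, but 0 passed over all genes or over the list alone; the largest were Oasl1 (1.97), Mx1 (1.76), Rsad2 (1.67) and Cmpk2 (1.61). The GTPases had a mean of 1.55, with 1 gene passing over all genes and 2 over the list alone (Gbp5 2.17, Gbp3 1.93, Gbp2 1.38). Of the chemokines 1 passed over all genes and 4 when adjusted over the list alone. Alternative activation had a mean of 0.73, with a positive difference in 4 of 4, and 0 passing over all genes and 3 over the list alone. Granulocyte and progenitor markers had a mean of 0.5, with a positive difference in 9 of 11 and 1 passing over the list alone. Without the LPS arrays, whose spread enters the fit, 68 genes were higher and 29 lower. That added Saa3 (2.96 ± 0.28), Cxcl10 (2.14 ± 0.37), Cxcl2 (2.10 ± 0.16), Ccl12 (1.71 ± 0.27), Smad6 (-1.61 ± 0.20), Mcoln3 (-1.55 ± 0.18) and Ebi3 (-1.20 ± 0.18). In that fit 13 effectors and 9 GTPases passed when adjusted over the list alone. Without the 1, 3 or 8 h arrays 8, 1 or 3 genes passed, and without either unstimulated WT array 46.

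With IFNb, 2 genes were higher and 1 lower in p50KO macrophages (179 at an unadjusted p under 0.05). They were Gbp2b (6.58 ± 0.73, adjusted p = 0.00458, at least 63.6-fold), Gdf3 (1.73 ± 0.16, adjusted p = 0.0017) and Eif4e (-1.70 ± 0.18, adjusted p = 0.00403). The effectors had a mean of 0.18, with a positive difference in 22 of 28 and 0 passing over all genes or over the list alone (Oasl1 1.58, Oas1g 0.49). The GTPases had a mean of 0.59, with a positive difference in 5 of 11 and Gbp2 at -0.36, and of -0.01 without Gbp2b; 1 passed over all genes and 1 over the list alone. Without the LPS arrays 5 genes were higher and 7 lower. That added Csprs (1.47 ± 0.19), Apoe, the apolipoprotein E gene (1.05 ± 0.13), Gpr84 (0.89 ± 0.12), Ebi3 (-2.09 ± 0.18), Mcoln3 (-1.84 ± 0.18) and Hscb (at least 2.38-fold lower, adjusted p = 0.0174). Without the 1 h or the 3 h arrays 1 or 0 genes passed, and without either unstimulated WT array 15. Before stimulation p50KO had 1 array, of the CpG series, so no test of that condition is given. Against the unstimulated WT array of that series 42 genes were at least 2-fold higher and 21 at least 2-fold lower in p50KO.

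With LPS, 214 genes were higher and 234 lower in p50KO macrophages (2053 at an unadjusted p under 0.05). Over the immediate-early genes, the p50KO array labelled LPS 1 h lay closer to WT LPS 3 h (root mean square difference 0.64 log2) than to WT LPS 1 h (2.25). Over all genes the one labelled LPS 3 h lay closest to WT LPS 8 h (r = 0.983 across genes, against 0.95 with its own time), but over the immediate-early genes it lay closest to its own time (0.67, against 0.91 with WT LPS 8 h). Gbp2b (9.73 ± 0.73, adjusted p = 0.000229, at least 548-fold), Klri1 (2.91 ± 0.55), the activin subunit gene Inhba (2.76 ± 0.27, adjusted p = 0.000861), and Rab38 (2.61 ± 0.26, adjusted p = 0.000861) were higher. So were Ifi214 (2.49 ± 0.59), Ptges, which makes prostaglandin E (2.39 ± 0.52), Phf11a (2.36 ± 0.53), Rasgrp1 (2.20 ± 0.37), Cav1 (2.18 ± 0.41) and Gfi1 (2.17 ± 0.37). Ppfia3 (-2.80 ± 0.54, at least 5.02-fold lower), Tpbg (-2.67 ± 0.47, at least 3.86-fold lower), Cd83, a marker of activated antigen-presenting cells (-2.51 ± 0.39), and Tnfsf9 (-2.5 ± 0.46) were lower. So were Batf (-2.21 ± 0.47), Cxcl1 (-2.13 ± 0.39), Dgat2 (-2.05 ± 0.43), Epb41l3 (-1.96 ± 0.23), Micall2 (-1.95 ± 0.26) and the anti-inflammatory cytokine gene Il10 (-1.90 ± 0.18, adjusted p = 0.000861). The effectors had a mean of 1.42, 28 of 28 with a positive difference, with 3 passing over all genes and 15 over the list alone (Ifit3 2.37, Ifit2 2.24, Mx1 2.23, Isg20 2.14). That mean was made of 3.26, 0.96 and 0.05 in the arrays labelled 1, 3 and 8 h. The GTPases had a mean of 2.16, with 1 and 6 passing. Of the immediate-early genes 5 were lower over all genes and 8 over the list alone (Egr1 -1.60, Fos -1.53, Zfp36 -1.41, Junb -1.22), and of the cell cycle list 3 and 11 (Rrm2 -1.44, Mcm3 -1.28). The inflammatory list had 3 genes higher and 2 lower over all genes, and 5 and 2 over the list alone. Of the chemokines 2 were lower over all genes and 3 over the list alone. The dendritic cell and MHC class II markers had a mean of 0.49, with 1 higher over all genes and 4 over the list alone. Granulocyte and progenitor markers had a mean of -0.59, with a positive difference in 0 of 11. NF-kB subunits and inhibitors had means of 0.25 with CpG, 0 with IFNb and -0.20 with LPS. Without the 1 h or the 3 h arrays 133 or 8 genes passed, and without either unstimulated WT array 694.

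Between the arrays of different stimuli the p50 difference differed for few genes. Between CpG and IFNb it differed for 2 genes (264 at an unadjusted p under 0.05), with Npy (-6.96 ± 0.55, adjusted p = 0.000408) and Apoe (-1.99 ± 0.25, adjusted p = 0.0211) lower in the CpG arrays. Between LPS and IFNb it differed for 4 genes (935), which were Inhba (2.82 ± 0.38), Rab38 (2.70 ± 0.36), Il10 (-1.93 ± 0.26) and Incenp (-1.57 ± 0.21), all at adjusted p = 0.0248. Between LPS and CpG 9 genes were higher and 11 lower (909), among them Npy (7.31 ± 0.55, adjusted p = 0.000241), Id1 (2.25) and Fkbp9 (2.31). The lower ones included Cxcl1 (-5.87 ± 0.55, adjusted p = 0.00115), Gadd45b (-2.33 ± 0.26), Il10 (-2.32 ± 0.26, adjusted p = 0.00455), Scd1 (-2.17), Zfp36 (-1.56) and Nfkbia, the gene of the NF-kB inhibitor IkB-alpha (-1.5 ± 0.24, adjusted p = 0.0376). CpG lay in another array series than LPS and IFNb, so the differences that involve CpG cannot be told apart from the series. For Npy the difference was there on the unstimulated arrays of the CpG series, at 4.48 in p50KO and 12.05 in WT. Across genes the p50 difference with CpG had r = 0.206 and rho = 0.0821 with that of IFNb, and 6 genes were at least 2-fold apart in both, 6 of them in the same direction; genes are not independent replicates. Without the 3 h arrays none of these 3 contrasts called a gene, and without either unstimulated WT array LPS against IFNb called 0 genes, CpG against IFNb 9 and LPS against CpG 39.

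LPS gave the broadest response of macrophages of both genotypes. The fits at 1 and 3 h include the p50KO arrays so labelled, which resembled later WT times over all genes. At 1 h 335 genes rose and 648 fell, at 3 h 1590 and 2385, and at 8 h 1795 and 2544 (limma, two-sided). With scaling to the 75th percentile the rises outnumbered the falls: 964 and 666, 2838 and 1830, and 2945 and 1932. At 1 h the chemokine genes Cxcl10 (8.15 ± 0.72, adjusted p = 5.56e-06), Cxcl2 (7.73), Cxcl1 (7.33 ± 1.31, adjusted p = 0.00373) and Ccl5 (5.92) rose. With them rose Ifnb1 (7.10 ± 0.48, adjusted p = 6.03e-07, at least 75.6-fold), Il1b (6.24 ± 0.39, at least 56.3-fold), the cytokine signal inhibitor gene Socs3 (6.19), Tnf (5.98 ± 0.31, adjusted p = 9.85e-08), Nfkbiz (5.92) and Ccrl2 (5.06). Cdca7 (-2.78), the cannabinoid receptor gene Cnr2 (-2.33) and Dusp6 (-2.33) fell. At 3 h Cxcl10 (8.92), Ccl5 (7.79), Saa3 (7.41), Il1b (7.34 ± 0.39, at least 120-fold), Gbp5 (6.63, at least 81.1-fold), Il27 (6.53), Cxcl9 (6.52, at least 61.2-fold), the endothelin gene Edn1 (6.36) and Cd69 (6.31) led the rises. Cdca7 (-4.35), the chemokine receptor gene Cxcr4 (-3.88), Bcl7a (-3.82), Anln (-3.51) and the mismatch repair gene Msh6 (-3.5) led the falls. At 8 h Saa3 (8.5), Gbp5 (7.21, at least 121-fold), the matrix protease gene Mmp14 (7.18), Fpr2 (6.74) and Cfb (6.70, at least 63.7-fold) were among the rises. St6gal1 (-5.15), Anln (-4.77), Pbk (-4.75), Rasgrp3 (-4.66), Cdca2 (-4.58), Rrm2 (-4.53) and Clspn (-4.40) led the falls. With the array series as a block 80 genes rose and 39 fell at 1 h, 541 and 688 at 3 h and 1128 and 1666 at 8 h, and Cxcl1 and Cdca7 at 1 h and Anln at 3 h missed the threshold. Fcer1g, at -6.65, -6.38 and -6.5 at the 3 times, was -0.12, 0.15 and 0.03 with the block. Without the p50KO LPS arrays 415 genes passed at 1 h. On the WT arrays alone 201 genes were at least 2-fold higher and 91 at least 2-fold lower at 1 h, 614 and 575 at 3 h and 1030 and 1271 at 8 h.

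With IFNb 50 genes rose and 22 fell at 3 h. Cxcl10 (6.25 ± 0.72, adjusted p = 0.0016), the antiviral GTPase genes Mx1 (5.25 ± 1.09, adjusted p = 0.043) and Mx2 (4.52), and Rsad2, which encodes viperin (4.38 ± 0.76, adjusted p = 0.0228), led the rises. Cd274, which encodes PD-L1 (3.71 ± 0.51), Isg15 (3.64 ± 0.70), Hap1 (3.24), Phf11d (2.96), Ifi47 (2.94) and Nrap (2.87 ± 0.35) followed. Spry3 (-1.71), Herpud1 (-1.57), Malt1 (-1.55) and Mafg (-1.42) led the falls. At 1 h 0 genes rose or fell in limma (1381 at an unadjusted p under 0.05), and at 8 h 5 rose and 4 fell, among them Nrap (2.02), Evi2 (1.48), Gja1 (-1.74), Gpr84 (-1.51) and Lipn (-1.38). On the WT arrays alone 28, 231 and 122 genes were at least 2-fold higher at 1, 3 and 8 h and 2, 36 and 34 lower. At 3 h Cxcl10 was at 7.55 there, Ifit3 at 6.49, Rsad2 at 6.37, Ifit2 at 6.12, Gbp2 at 4.8 and Irf7 at 4.67, and Mx1 was at least 43.7-fold higher. With the array series as a block 0 genes passed at 1 h (81 at an unadjusted p under 0.05), 3 at 3 h, Cxcl10 and Rsad2 among them, and 0 at 8 h (286). The counts moved with the baseline. Without the unstimulated WT array of 1 or the other series the counts ran from 0 to 1200 at 1 h, from 9 to 1686 at 3 h and from 0 to 1632 at 8 h. Without the p50KO LPS arrays they were 6, 1381 and 986.

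CpG raised few genes, inhibitors of NF-kB and cytokines among them. At 1 h 0 genes passed in limma (55 at an unadjusted p under 0.05), at 3 h 12 rose and 0 fell (205), and at 8 h 38 rose and 0 fell (487). At 3 h Tnf (2.95 ± 0.31, adjusted p = 0.000658), Gpr84 (2.87 ± 0.25, adjusted p = 9.44e-05), the NF-kB inhibitor gene Nfkbie (2.78 ± 0.31) and the receptor gene Tlr2 (2.65) rose. So did the adhesion molecule gene Icam1 (2.45), the NF-kB subunit gene Relb (2.30), Nfkbiz (2.24), Il1b (2.18, at least 3.38-fold), Clec4e (2.16) and Nfkbia (2.11). At 8 h Saa3 (5.75 ± 0.80, adjusted p = 0.00305), Gpr84 (4.14 ± 0.25, adjusted p = 6.76e-07), Cxcl2 (3.97 ± 0.68), and Cxcl10 (3.87 ± 0.72, adjusted p = 0.0289) rose. So did H2-M2 (3.5, at least 8.37-fold), Clec4e (3.45 ± 0.28), Cdc42ep2 (3.28), the formyl peptide receptor gene Fpr2 (3.24), Tnf (3.24 ± 0.31) and Nfkbie (2.90). With the array series as a block 5 genes passed at 3 h and 20 at 8 h, and Tlr2, Relb, Nfkbiz, Il1b and Nfkbia at 3 h and Cxcl2 and Cxcl10 at 8 h missed the threshold. Without either unstimulated WT array 5 to 6 genes passed at 3 h and 20 to 21 at 8 h, and without the p50KO LPS arrays 27 and 178. On the WT arrays alone 4, 39 and 81 genes were at least 2-fold higher at 1, 3 and 8 h, against 5, 75 and 246 on the p50KO arrays. Averaged over the times, 2491 genes were higher and 3159 lower with LPS than with CpG, 1480 and 2365 with LPS than with IFNb, and 1918 and 1773 with CpG than with IFNb. The balance turned with the scaling: to the 75th percentile these were 3836 and 2519, 2053 and 1538, and 2043 and 2847, and with the authors' values 1373 and 4187, 1632 and 1686, and 3931 and 558. With the array series as a block they were 53 and 7, 1579 and 2575, and 1 and 0 (156 at an unadjusted p under 0.05). That block is set by 1 unstimulated WT array, so its low counts across series cannot tell a series effect from a lack of precision.

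Grouped by list, the antiviral effectors rose with LPS and IFNb. The LPS counts at 1 and 3 h include the p50KO arrays that resembled later WT times. Of 28 effectors 2, 24 and 28 rose with LPS at 1, 3 and 8 h over all genes (2, 25 and 28 over the list alone; 1, 25 and 28 with the series as a block). With IFNb 4 rose at 3 h (22 over the list alone, 1 with the block) and 0 at 8 h (8 over the list alone), and with CpG 0 at any time. On the WT arrays alone, against the unstimulated array of their series, IFNb left 28 of 28 effectors at least 2-fold higher at 3 h and 27 at 8 h. The 11 GTPases showed 1, 9 and 10 rises with LPS, 1 with IFNb at 3 h (9 over the list alone) and 0 with CpG (3 over the list alone at 8 h). NF-kB subunits and inhibitors were shared by LPS (10, 13 and 13 of 13) and CpG (4 at 3 h and 7 at 8 h; 8 and 9 over the list alone; 1 with the block at each time). With IFNb limma called 0 of them over all genes or the list alone, and of MHC class I presentation 0 over all genes at any time (7 higher and 1 lower over the list alone at 3 h, 10 higher at 8 h). Of the inflammatory list 9, 14 and 13 of 15 rose with LPS and 2 with CpG at 3 and at 8 h. Of the chemokines 8, 13 and 13 of 15 rose with LPS, 2 with CpG at 8 h (6 over the list alone) and 4 with IFNb at 3 h (6 over the list alone). LPS also raised 2, 9 and 10 genes of the interferon pathway, 2, 13 and 13 of MHC class I presentation, 4, 8 and 10 of the TLR components and 4, 6 and 6 of the dendritic cell and MHC class II markers. With the block these 4 lists had 2, 5 and 8, then 0, 10 and 13, then 1, 6 and 10, and 0, 4 and 5. With the block LPS raised 0, 8 and 10 GTPases and 8, 11 and 13 NF-kB subunits and inhibitors. It then raised 3, 12 and 13 genes of the inflammatory list and 5, 12 and 13 chemokines. The immediate-early genes rose most often at LPS 1 h (7 of 14; 9 over the list alone). The cell cycle list fell with LPS, 12 of 13 at 3 h (0 with the block) and 13 of 13 at 8 h (11 with the block). Granulocyte and progenitor markers showed 8, 7 and 4 rises with LPS over all genes, of which 0, 1 and 0 passed with the block.

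**Figure D3:**
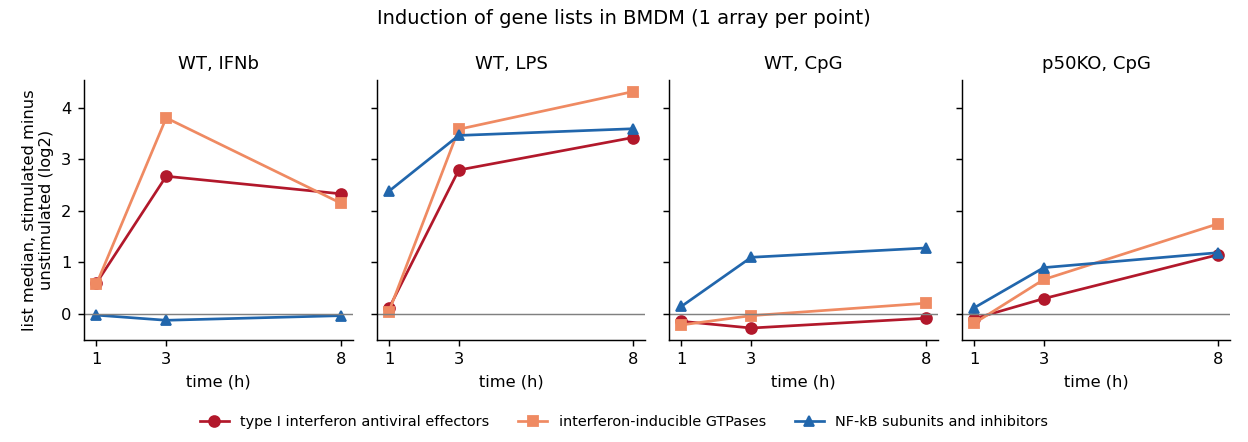
Median log2 induction of 3 gene lists over the unstimulated array of the same genotype and series at 1, 3 and 8 h in macrophages, 1 array per point. The antiviral effectors reach 2.67 with IFNb and 3.42 with LPS in WT cells, stay at -0.08 at CpG 8 h in WT and reach 1.15 at CpG 8 h in p50KO cells.

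Set against the unstimulated array of its own genotype, CpG induced interferon-response genes in p50KO macrophages more than in WT, on 1 array per condition and so with no test. The median induction of the 28 effectors by CpG was -0.14, -0.27 and -0.08 log2 at 1, 3 and 8 h in WT, with 0 of 28 at least 2-fold up at 8 h. It was -0.09, 0.30 and 1.15 in p50KO, with 20 of 28. The median difference between genotypes was 0.01, 0.52 and 1.5, at percentiles 51.3, 100 and 100 of 10000 random lists matched on mean expression. Random lists hold genes that do not move together, so a list of co-regulated genes reaches an extreme easily. At 8 h MHC class I presentation, the inflammatory list, the chemokines and the TLR components also lay at percentile 100, and the cell cycle at 0. The percentile does not single out the interferon genes. At 8 h the p50KO induction exceeded that of WT by 3.42 for Gbp3, 3.02 for Ccl5, 2.78 for Gbp2, 2.76 for Ifit3, 2.51 for Ifit2 and 2.42 for Isg15. Gbp2b, below background in WT, was induced by 3.65 in p50KO. Gbp5, the complement gene Cfb and Tsc22d1 were below background before stimulation and were induced at least 25-fold, 4.42-fold and 3.36-fold in p50KO. In WT Gbp5 was induced at least 1.79-fold, and the other 2 stayed below background. Induction was lower in p50KO for Ube2c (-1.97), Dusp1 (-1.55), Ccna2 (-1.40) and Fos (-1.38). At 1 h Cxcl1 was induced by 2.51 in p50KO and stayed below background in WT. At 3 h it reached 10.38 in p50KO and 6.26 in WT, Gbp5 was induced at least 5.98-fold in p50KO alone, and Gbp3 (1.88), Gbp2 (1.51), Socs3 (1.47) and Ifit3 (1.33) differed most among the others. The GTPases had a median of 0.21 in WT and 1.75 in p50KO at 8 h, MHC class I presentation 0.25 and 0.72 and the chemokines 0.34 and 0.64. NF-kB subunits and inhibitors had 1.28 in WT (8 of 13 at least 2-fold up) and 1.19 in p50KO (7), and the cell cycle list -0.21 and -0.74. The dendritic cell and MHC class II markers had 0.17 and 0.70, and granulocyte and progenitor markers -0.09 and -0.10, though the latter lay higher in p50KO by a mean of 0.50 over the CpG arrays (9 of 11 genes).

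Without the type I interferon receptor, much of the interferon part of the LPS response at 3 h was missing, on 1 IFNARKO array per condition and with no test. The IFNARKO arrays were taken as a series of their own, so their differences in level from WT also cross series. Ifnar1 did not pass the detection filter and was not measured. Of 627 genes induced at least 2-fold in WT macrophages, 178 (28.4%) had an induction at least 2-fold lower in IFNARKO, 342 had one that was not lower or lower by less than 1.5-fold, and 107 lay between. The 178 became 97 with the authors' values, 175 without the unstimulated WT array of the CpG series and 287 without that of the LPS series. Mx1 (at least 70.8-fold), the chemokine gene Cxcl9 (at least 58.1-fold), Ccl8 (at least 7.68-fold) and Isg20 (at least 6.97-fold) were induced in WT and stayed below background in IFNARKO. So did Mx2 and Irf7, a transcription factor of interferon genes, which were induced by 6.09 and 3.12 log2 in WT. The nitric oxide synthase gene Nos2 was induced at least 7.82-fold in WT and by 0.55 log2 in IFNARKO, and Batf2 reached 10.38 in WT and 5.12 in IFNARKO. The induction differed by -4.58 for Igtp, -4.00 for Ifi47, -3.88 for Irgm2, -3.54 for Ifi202b, -3.41 for Fcgr1, -2.97 for Irf8 and -2.67 for the peptide transporter gene Tap1. Of the inflammatory list 3 of 15 genes had an induction at least 2-fold higher in IFNARKO and 4 at least 2-fold lower, against the unstimulated WT array of the LPS series, and of NF-kB subunits and inhibitors 0 and 1 of 13. Tnf was induced by 6.11 in WT and 6.73 in IFNARKO, Nfkbia by 4.35 and 4.18, Tnfaip3 by 4.26 and 4.16 and Ccl2 by 1.86 and 1.95. Il6, Il1b and Ifnb1 were below background before stimulation and reached levels of 10.14, 12.13 and 9.89 in WT and 10.16, 13.04 and 8.52 in IFNARKO. The induction of Il10 differed by -1.81 and that of Bcl3 by -1.22. Induction was higher in IFNARKO for Chac1 (2.77), Rsad2 (2.41) and Ccl5 (1.65). Oasl2 and Gfi1 were induced at least 37.5-fold and 5.82-fold in IFNARKO, against 1.54 and 0.54 log2 in WT. By level at 3 h the colony-stimulating factor gene Csf2 (at least 7.52-fold), Marco (at least 4.89-fold), Flrt3 (3.13 log2) and Cxcl1 (1.13 log2) were higher in IFNARKO, as was Fcer1g (at least 923-fold), which also differed between the series of WT arrays. For Rsad2 the unstimulated IFNARKO level was lower, at 5.44 against 10.78 and 8.50 on the WT arrays, and its level at 3 h was 13.2 against 14.99 in WT.

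The classes rest on fold induction alone. Effectors such as Ifit3, Isg15, Oasl1 and Rsad2 started lower in IFNARKO than in WT, and a lower start can hide a dependence on the receptor. By list, 15 of 24 induced effectors were dependent on the receptor and 8 were not, against 1 and 11 of 12 NF-kB subunits and inhibitors. The GTPases had 4 and 4 of 8, the interferon pathway 4 and 3 of 8, and MHC class I presentation 4 and 5 of 10. The chemokines had 3 and 10 of 14, the inflammatory list 3 and 9 of 13 and the TLR components 0 and 5 of 6. The immediate-early genes had 2 and 2 of 5, the dendritic cell markers 0 and 3 of 3, and granulocyte and progenitor markers 6 and 0 of 10. Against the unstimulated WT array of the LPS series alone, 0 of 11 granulocyte and progenitor markers had an induction at least 2-fold lower in IFNARKO. Of heat shock and stress 1 and 1 of 2 were so divided, 1 macrophage marker was dependent, 1 gene of alternative activation lay between, and no cell cycle gene or gene near the disrupted locus was induced. The p50 difference was then compared between the receptor-dependent and the receptor-independent genes on the 6 CpG and IFNb conditions, which took no part in that division. It was larger for the dependent genes by 0.09 log2 (SD 0.13), in 6 of 6 conditions (exact two-sided sign-flip p = 0.0312, the smallest 6 conditions can give). With CpG the dependent genes had a mean p50 difference of 0.51 and the independent 0.35, a gap of 0.08, 0.07 and 0.35 at 1, 3 and 8 h, and with IFNb 0.02 and -0.01. The gap over the 6 conditions missed the threshold (exact sign-flip p = 0.0625) without background correction, with the stricter detection filter, with 3-fold classes and with the baseline of the same series. The gap was -0.01 (exact p = 0.75) without the unstimulated WT array of the LPS series.

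**Figure D4:**
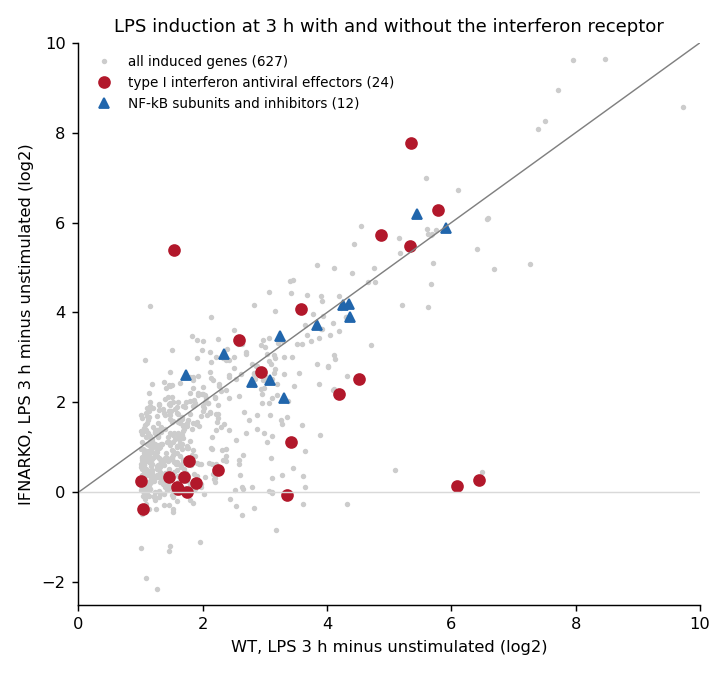
Log2 induction by LPS at 3 h in WT (horizontal) and IFNARKO (vertical) macrophages for the 627 genes induced at least 2-fold in WT, 1 array per condition, with the line of equal induction. Of the antiviral effectors 15 of 24 were dependent on the receptor by fold induction, while 11 of 12 NF-kB subunits and inhibitors were not. Some effectors started at a lower level in IFNARKO.

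In fibroblasts the p50 difference could not be told apart from the array series. The labels name LPS for both genotypes, but the number of probes above background split the arrays by genotype, so the WT LPS, WT IFNb and p50KO arrays were taken as series, each with 1 genotype. limma called 2329 genes higher and 2634 lower in p50KO over 4 matched conditions, but 0 genes with the series as a random block (correlation 0.773, 1682 genes at an unadjusted p under 0.05). All p50KO arrays stand in 1 series, so that block leaves little to test the genotype with, and its 0 calls decide nothing about p50. On the unstimulated arrays the root mean square difference was 0.908 and 0.888 log2 between p50KO and either WT array and 0.928 between the WT arrays. Further, 738 genes were above background on all p50KO arrays and on no WT array, against 1 the reverse. Gbp2b was higher in p50KO fibroblasts (5.44 ± 1.24, adjusted p = 0.0119, at least 18-fold), as were Nono (4.58 ± 0.62), the amino acid transporter gene Slc3a2 (4.50), the tubulin gene Tuba1a (4.45), and Mdh2 (4.38). Others were Gng5 (4.34), Calm2 (4.22), Strn3 (4.19), Cct5 (4.18) and the chromatin protein gene Hmgb1 (4.16). Adh7 (-3.87 ± 0.28, adjusted p = 0.000671, at least 9.63-fold), Serpina3n (-3.51), Crebbp (-3.03), the BMP antagonist gene Grem1 (-2.88), Nr1d2 (-2.37), Bcat2 (-2.31), Npy (-2.23), Ap2a1 (-2.20), Scaf1 (-2.16) and Arsj (-2.13) were lower. With the random block each of these 20 genes missed the threshold (adjusted p 0.12 to 0.494). Without the LPS 1 h or 3 h arrays 3263 or 3092 genes passed.

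The fibroblast lists gave no call in camera (smallest adjusted p = 0.73 with the preset and 0.942 with an estimated correlation), and 4 conditions are too few for the exact test to pass. The means without the block, with counts over all genes, were 0.46 for the 22 effectors (3 higher and 1 lower, 0 over the list alone). They were 0.60 for the 10 GTPases (2 and 2), with Gbp2b alone at 5.44, and 0.08 for the interferon pathway (2 and 3 of 13). They were 0.36 for MHC class I (4 and 1 of 13; H2-K1 2.82), 0.25 for NF-kB subunits and inhibitors (3 and 3 of 12; Nfkbia 4.05) and 0.13 for the chemokines (4 and 1 of 16; Cxcl5 2.82). They were -0.51 for the inflammatory list (1 and 4 of 12; Csf3 -1.97, Csf2 -1.69, Ptgs2 1.76), -0.22 for the immediate-early genes (3 and 5 of 13; Junb -2.07) and 0.31 for the TLR components (3 and 1 of 12). Further means were 0.56 for the fibroblast markers (5 and 2 of 12; Col3a1 3.11, Postn 2.43), 0.70 for the cell cycle (5 and 0 of 13; Mcm6 3.48, Pcna 3.4) and 0.23 for genes near the disrupted p50 locus (4 and 2 of 13). Small lists had 1.01 for the macrophage markers (1 and 0 of 4; Ctss 3.6), -0.48 for the dendritic cell markers (0 and 2 of 4) and 0.14 for the granulocyte markers (1 and 1 of 3). Alternative activation had -0.08 (1 and 0 of 3) and heat shock and stress -0.21 (1 and 1 of 6). The GTPase mean was not computed without Gbp2b in MEF, so it does not show a raised family. After Gbp2b its largest members were Ifi47 (1.25), Iigp1 (1.19) and Irgm1 (-1.06). Of lists with under 3 measured members, Ifnb1 (1.22 ± 0.32, adjusted p = 0.0201), Ifna6 (0.46 ± 0.11, adjusted p = 0.0124), the lymphocyte gene Ms4a1 (0.49 ± 0.11, adjusted p = 0.0108) and the mast cell gene Mcpt8 (2.12 ± 0.37, adjusted p = 0.0048) were higher. They missed the threshold with the random block (adjusted p = 0.556, 0.472, 0.455 and 0.235).

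LPS raised cytokine and chemokine genes in fibroblasts from 1 h and interferon-response genes from 3 h. At 1 h 16 genes rose and 0 fell (231 at an unadjusted p under 0.05), at 3 h 284 and 144, and at 8 h 588 and 509. At 1 h Tnf (5.40 ± 0.26, adjusted p = 0.00184, at least 19.2-fold), Cxcl2 (5.30 ± 0.40, at least 21.7-fold), Cxcl1 (4.51), the ubiquitin-editing NF-kB inhibitor gene Tnfaip3 (4.19), Ccl4 (3.88), Cd83 (3.42), Ccrl2 (3.36), Il1b (3.27), Ier3 (3.25) and Tnfsf9 (3.10) rose. At 3 h Cxcl9 (8.40 ± 0.21, adjusted p = 6.4e-05, at least 225-fold), Rsad2 (7.91 ± 0.50, adjusted p = 0.000648), Cxcl10 (7.6), Cd69 (6.86), Cd274 (6.43), Ccl2 (6.28), Gbp5 (6.27), Ccl5 (6.24) and Tnf (6.09) led the rises. Ppp1r3c (-3.43), Cdc42ep3 (-2.33), the clock gene Dbp (-2.21), Fgf21 (-2.06) and Id1 (-1.78) fell. At 8 h Cxcl9 (9.37 ± 0.21, adjusted p = 3.09e-05, at least 443-fold), Il1b (8.46, at least 158-fold), Ccl5 (7.89), Cxcl10 (7.71), Saa3 (7.29), Rsad2 (6.73), Il1a (6.66) and Gbp5 (6.64) rose. The matrix signalling gene Ccn2 (-3.44), Ldb2 (-3.4), Gucy1a1 (-3.36) and the Wnt-pathway receptor gene Lgr5 (-2.89) fell. Of the 22 effectors 0, 12 and 17 rose at 1, 3 and 8 h (0, 17 and 19 over the list alone), of 10 GTPases 0, 8 and 8, and of 12 NF-kB subunits and inhibitors 1, 10 and 11. Of 16 chemokines 3, 9 and 12 rose and of 12 inflammatory genes 2, 4 and 8. MHC class I presentation had 0, 6 and 9 of 13 and the immediate-early genes 3, 4 and 6 of 13, while of 12 fibroblast markers 0 changed in limma at any time. With the series as a random block 45, 1303 and 2707 genes passed at 1, 3 and 8 h, and without the IFNb series 53, 1755 and 3315.

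**Figure D5:**
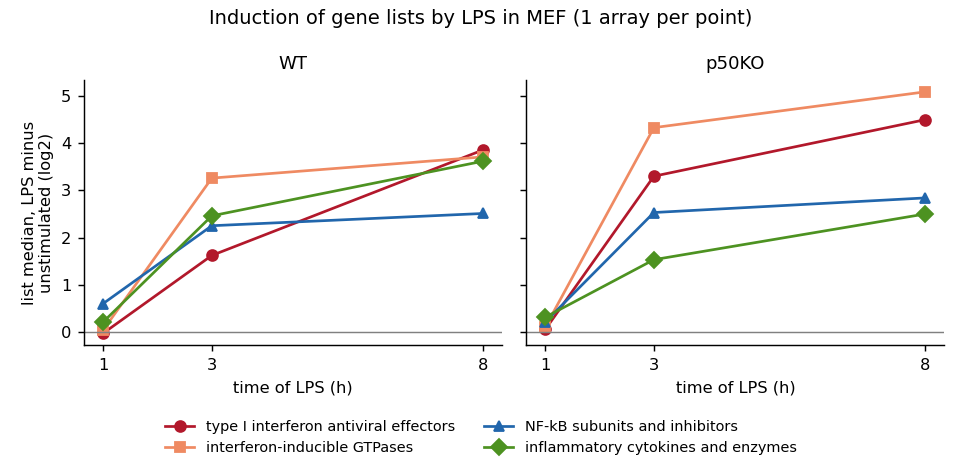
Median log2 induction of 4 gene lists by LPS at 1, 3 and 8 h over the unstimulated array of the same genotype in fibroblasts, 1 array per point. At 3 h the antiviral effectors reach 1.62 in WT and 3.30 in p50KO cells, while the inflammatory list reaches 2.46 in WT and 1.53 in p50KO cells.

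Against the unstimulated array of their own genotype, p50KO fibroblasts had a higher induction of the effectors and GTPases by LPS at 3 and 8 h and a lower induction of the inflammatory list, on 1 array per condition, with no test and with each genotype in its own series. The effectors had medians of -0.03, 1.62 and 3.86 at 1, 3 and 8 h in WT and 0.05, 3.30 and 4.50 in p50KO. The induction was at least 2-fold higher in p50KO for 14 of 22 at 3 h and 8 of 22 at 8 h. The GTPases had 3.26 and 3.71 in WT and 4.33 and 5.09 in p50KO at 3 and 8 h. The inflammatory list had 2.46 and 3.62 in WT and 1.53 and 2.50 in p50KO, at least 2-fold lower in p50KO for 7 of 12 at both times, but 0.21 and 0.31 at 1 h. The interferon pathway had 1.34 and 1.05 in WT and 1.29 and 1.56 in p50KO at 3 and 8 h, with a median difference of 0.22 and -0.10. The level of Csf3, which encodes G-CSF, was 9.08 and 10.63 in WT and 4.69 and 6.53 in p50KO. NF-kB subunits and inhibitors had 2.25 and 2.51 in WT and 2.53 and 2.84 in p50KO, and the chemokines 4.94 and 5.50 against 4.89 and 5.35.

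IFNb for 8 h induced the antiviral program in WT fibroblasts, with 1 stimulated array and no test. Set against the mean of both unstimulated WT arrays, 683 genes were at least 2-fold higher and 414 at least 2-fold lower; against the array of its own series these were 373 and 86. Rsad2 (7.51), Cmpk2 (6.54), Ifit2 (6.09) and Ccl8 (5.34) were among the largest differences. So were genes below background without IFNb: Cxcl10 (at least 252-fold), Cxcl9 (at least 44.2-fold), the oligoadenylate synthetase-like gene Oasl1 (at least 42.7-fold), Tgtp1 (at least 28.9-fold), Mx1 (at least 27-fold) and Phf11a (at least 16.8-fold). Sbk1 (-2.88), Zcchc18 (-2.76), the iron exporter gene Slc40a1 (-2.65), Msx1 (-2.54), the elastin gene Eln (-2.39) and Dlk1 (-2.37) were lower. Within its series the median induction was 3.96 for the effectors (21 of 22 at least 2-fold up), 4.37 for the GTPases (9 of 10), 2.04 for MHC class I presentation (10 of 13) and 0.87 for the chemokines (8 of 16). It was 0.16 for NF-kB subunits and inhibitors and 0.04 for the inflammatory list.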

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

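The tests of other splits of the samples were chosen before the results were seen; the tests of the p50KO LPS arrays and of the CpG arrays were chosen after.

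By a test of the difference itself, the p50 difference in macrophages differed between the arrays of different stimuli. CpG lay in another array series than LPS and IFNb, so its contrasts cannot be told apart from the series. Between CpG and IFNb 2 genes differed, Npy by -6.96 and Apoe by -1.99 log2. Before any CpG, Npy was already at 4.48 on the p50KO array of that series, against 12.05 in WT. On the p50KO array given IFNb for 3 h it was at 10.44, so its difference is not a response to CpG. Between LPS and IFNb 4 genes differed, with Inhba at 2.82. Between LPS and CpG 20 genes differed, with Il10 at -2.32, Cxcl1 at -5.87 and Nfkbia at -1.5. The splits of the arrays within conditions were too few for a share under 0.05: 1 of 10 splits gave as many genes for each contrast, the real one, with 0, 0 and 4 genes as the highest of the others. For the stimuli taken singly 1 of 4 splits did so, again the real one and again too few, with 29 genes for CpG, 448 for LPS and 3 for IFNb against 0, 162 and 0 in the others. For the p50 difference over all conditions 1 of 100 splits, the real one, gave as many as 42 genes, and the highest other gave 6. That argues against a chance split of these arrays. It cannot exclude a chance difference between the animals or cultures of each genotype, since the labels name no separate ones.

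A chance split is argued against for the contrasts of the agents too, with the same limit: 1 of 32 splits, the real one, gave as many genes. LPS against CpG called 5650 genes and the highest other split 3946, LPS against IFNb 3845 and 3334, and CpG against IFNb 3691 and 119. In MEF 1 of 24 splits, the real one, gave as many as 4963 genes, but another gave 4262. Other splits keep part of the real labels, so their many calls may come from the real difference or from a structure beyond the labels. The splits cannot tell these apart. With the array series as a block LPS against CpG called 60 genes, CpG against IFNb 1 and LPS against IFNb, within 1 series, 4154. In BMDM that block is set by 1 unstimulated WT array, so its few calls across series cannot tell a series effect from a lack of precision. The MEF genotypes called 0, where each series held 1 genotype.

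The p50KO array labelled LPS 1 h resembled WT LPS 3 h, and that labelled LPS 3 h resembled WT LPS 8 h over all genes, while that labelled LPS 8 h lay closest to its own time. This bears on Inhba, Il10, Cxcl1 and Nfkbia and on the 448 LPS calls. It also bears on the macrophage LPS responses at 1 and 3 h over both genotypes, which include these p50KO arrays. An effect of array series or normalization was argued against, since 3 of 3 p50KO IFNb arrays of the same series were closest to the WT array of their own time. For the array labelled LPS 1 h a longer exposure than the label states fits the immediate-early genes, whose distance to WT LPS 3 h was 0.283 of that to WT LPS 1 h, and remains a candidate explanation. Ifnb1 went the other way, at 11.74 on that array against 11.14 at 1 h and 9.89 at 3 h in WT. For the array labelled LPS 3 h it stays open: r across all genes was highest with WT LPS 8 h (0.983 against 0.95), but over the immediate-early genes the distance to WT LPS 8 h was 1.37 times that to WT LPS 3 h. A faster interferon response without p50 stays open, since with 1 array on each side its test could not decide either way. In the p50KO array labelled LPS 1 h 28 of 28 effectors were higher than in the p50KO array given IFNb for 1 h. The mean difference was 2.24 log2, against -0.64 in WT. It was 0.2 against the p50KO array given IFNb for 3 h. The longer exposure has the same limit, being read from 1 p50KO array. A changed course of the response without p50 stays open and untested. The p50KO array given CpG for 3 h, of the other series, also lay closest to WT CpG 8 h (r = 0.991 against 0.99; immediate-early distance 0.65 against 0.75), while in MEF the p50KO inductions were closest to their own times (r = 0.552, 0.858 and 0.87 across genes).

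The antiviral effectors lay higher in p50KO than in WT macrophages given CpG by a mean of 0.22, 0.75 and 1.67 log2 at 1, 3 and 8 h, on 1 array per genotype and time and with 0 of 28 genes called. A difference present before stimulation was argued against by the median gap of 1.5 log2 between the genotypes' inductions of the effectors at 8 h. Other cell types in the p50KO cultures stay open, since the marker lists moved apart. Before stimulation the granulocyte and progenitor list was 0.48 ± 0.16 higher in p50KO (0.33 ± 0.16 at CpG 8 h). The dendritic cell and MHC class II list was 0.14 ± 0.08 higher (0.72 ± 0.13 at CpG 8 h). These errors are over the 11 and 8 genes of the lists on 1 array per genotype and measure no spread between samples. Mice of another strain background in the CpG series stay possible. There 1 gene, Ifi202b, was at least 8-fold apart in all 4 pairs of that series and under 2-fold apart in all 3 IFNb pairs, though it is itself interferon-inducible. Npy, at a mean of -7.56 in that series and -0.6 with IFNb, met only the first part of this rule. The rule was chosen after the results were seen and 1 gene met it, so it cannot weigh the explanation. A release of interferon genes from p50 is therefore consistent with these values but may be told from a strain difference or a change in cell types only with further samples.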

How the results depend on the processing

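The array series as a block or random block, each series alone, the fits without the LPS arrays or without the p50KO LPS arrays and the baseline of the same series were tests chosen after the results were seen; the others were planned. Except where a sentence gives one, the cause was not tested. Of the recomputed results that answer a comparison, 209 stayed within 1.5 times or on the same side of the threshold, 117 moved further, 5 lost the threshold and 1 turned its sign. Of the named genes 2628 recomputed values kept direction and call, 593 lost the call and 2 turned, both Fcer1g. Of the list values 245 were counted as unchanged, 7 lost the call and 8 moved. That count does not follow the sign of lists that were not called. Without the LPS arrays the mean of the cell cycle list went from -0.23 to 0.04. That of the immediate-early genes went from -0.19 to 0.10 and that of the granulocyte and progenitor markers from -0.16 to 0.03. Signal over background limits dim genes: genes below background on all arrays of a group have only a bound, and 40.7 to 47.8% of the probes passed on a BMDM array. The block by chip was not run, since the files name no chip. The p50 difference was matched by condition; no pairing by replicate was possible, since 1 array stands for every group but the unstimulated WT.

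Scaling changed the response counts. Quantile normalization without background correction called 7 genes at CpG 3 h, 21 at CpG 8 h, 26 at IFNb 3 h (23 higher and 3 lower) and 2 at IFNb 8 h, and left 686 genes at 2-fold for IFNb in MEF. The authors' values called 1 gene for the p50 difference between CpG and IFNb, 6 at CpG 3 h, 12 at IFNb 3 h (11 and 1) and 0 at IFNb 8 h, and made 97 genes receptor-dependent. Scaling to the 75th percentile called 7 genes between CpG and IFNb (3 and 4) and 0 between LPS and IFNb, 1 at CpG 1 h, 35 at IFNb 3 h (32 and 3), 0 at IFNb 8 h and 1630 at LPS 1 h. That scaling moved the median of all genes by 0.13, 0.23 and 0.23 log2 at LPS 1, 3 and 8 h, and the calls there were 964 higher and 666 lower, 2838 and 1830, and 2945 and 1932, against 335 and 648, 1590 and 2385, and 1795 and 2544. LPS against CpG then had 3836 and 2519 (against 2491 and 3159), LPS against IFNb 2053 and 1538 (against 1480 and 2365) and CpG against IFNb 2043 and 2847 (against 1918 and 1773). The authors' values moved the median by -0.15, -0.12 and -0.13 at IFNb 1, 3 and 8 h. They gave 10 higher and 21 lower for the p50 difference (against 19 and 23), 6 and 12 for LPS against CpG in it (against 9 and 11), 264 and 1052 at LPS 1 h, 1373 and 4187 for LPS against CpG, 1632 and 1686 for LPS against IFNb, and 3931 and 558 for CpG against IFNb. In MEF they gave 338 and 102 at LPS 3 h, 715 and 373 at LPS 8 h and 597 and 169 for IFNb. For the p50 difference with IFNb the splits were 1 and 1 without background correction and 2 and 2 with either other scaling (against 2 and 1), and without background correction 1 and 2 for CpG against IFNb and for LPS against IFNb.

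With no detection filter, which adds genes to the adjustment, 21 genes passed for the p50 difference, 285 for LPS, 1 between CpG and IFNb and 0 between LPS and IFNb. The same setting gave 5 at CpG 3 h, 17 at CpG 8 h, 20 at IFNb 3 h, 2 at IFNb 8 h and 4 at LPS 1 h in MEF. With the mean of a gene's probes 1 gene passed at IFNb 8 h.

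Leaving out arrays moved the p50 calls both ways. Over all conditions, without the CpG arrays 10 genes passed, without the 1, 3 or 8 h arrays 11, 12 and 15, without the unstimulated arrays 25 and with no condition term 13. The CpG series alone gave 595 and the LPS and IFNb series alone 15. Without 1 h the calls were 8 for CpG, 1 for IFNb, 133 for LPS, 1 between CpG and IFNb and 6 between LPS and CpG. Without 3 h they were 1, 0 and 8 for CpG, IFNb and LPS and 0, 0 and 0 for the differences. Without 8 h they were 3 for CpG, 11 between LPS and IFNb and 12 between LPS and CpG. Without the LPS arrays they were 97 for CpG, 12 for IFNb and 6 between CpG and IFNb, and 0 lists passed; 0 lists passed in the LPS and IFNb series alone, where 6 conditions are few.

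Leaving out either unstimulated WT array in turn gave 44 to 46 genes for the p50 difference, 46 to 46 for CpG, 15 to 15 for IFNb and 694 to 694 for LPS. Between CpG and IFNb it gave 9 to 9, between LPS and IFNb 0 to 0 and between LPS and CpG 39 to 39. The responses ranged over 0 to 0, 5 to 6 and 20 to 21 for CpG at 1, 3 and 8 h, 0 to 1200, 9 to 1686 and 0 to 1632 for IFNb and 360 to 2373, 3115 to 4445 and 3853 to 4624 for LPS. The agents ranged over 5639 to 5796 for LPS against CpG, 3802 to 4154 for LPS against IFNb and 3690 to 3909 for CpG against IFNb. In MEF the ranges were 4501 to 6776 for the p50 difference, 13 to 53, 290 to 1755 and 710 to 3315 for LPS and 459 to 2239 for IFNb. Induced genes ranged over 614 to 767 and receptor-dependent ones over 175 to 287. The lists that passed were 3 to 3 in BMDM and 0 to 0 in MEF. In these fits the lone remaining unstimulated WT array is assumed to vary like the other groups. By stimulus, the unstimulated arrays have a genotype term of their own, so leaving out either array gives the same contrasts. The equal counts there were fixed in advance, and in both cases the spread between those WT arrays leaves the error.

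The array series as a block left 5 and 20 genes for CpG at 3 and 8 h, 3 and 0 for IFNb, 119, 1229 and 2794 for LPS at 1, 3 and 8 h, 60 for LPS against CpG and 1 for CpG against IFNb. In BMDM that block is set by 1 array, the unstimulated WT array of the LPS series. Within a series it repeats the fit without that array. Fcer1g turned from a fall to 0.15 at LPS 3 h and 0.03 at 8 h, with adjusted p = 0.793 and 0.961. Without the p50KO LPS arrays 2, 27 and 178 genes passed for CpG, 6, 1381 and 986 for IFNb and 415 for LPS 1 h. WT arrays alone had 4, 40 and 92 genes at 2-fold for CpG, 30, 267 and 156 for IFNb and 292, 1189 and 2301 for LPS. In MEF the p50 difference called 3263 genes without LPS 1 h, 3092 without LPS 3 h and 0 with the random block, where the LPS times called 45, 1303 and 2707, and without the IFNb series they called 53, 1755 and 3315.

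The gap in the p50 difference between receptor-dependent and receptor-independent genes was 0.08 without background correction, 0.09 with the stricter detection filter, 0.13 with 3-fold classes and 0.1 with the baseline of the same series, each at an exact p of 0.0625. Leaving out either unstimulated WT array gave -0.01 to 0.1.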

Other observations

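The tests of the chromosome of the called genes were chosen after the result was seen.

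Interferon-response genes differed between macrophages before any stimulus. On the unstimulated IFNARKO array Ifit3 was at 5.17 log2, against 10.77 and 7.88 on the WT arrays, Irf7 at 4.36 against 8.28 and 5.85, Isg15 at 5.56 against 8.69 and 7.14, Oasl1 at 4.46 against 8.43 and 5.47 and Rsad2 at 5.44 against 10.78 and 8.50. The higher WT value belonged to the CpG series each time, so the 2 WT arrays differed by more than 1 log2 in these genes without stimulation.

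Ifnb1, the interferon beta gene, was at 11.14, 9.89 and 6.29 at 1, 3 and 8 h of LPS in WT macrophages and at 11.74, 8.38 and 8.48 on the p50KO arrays so labelled. With CpG it was at 4.23, 4.29 and 4.31 in WT and 4.43, 4.64 and 5.10 in p50KO, and with LPS at 3 h in IFNARKO at 8.52. In fibroblasts LPS gave 5.65, 6.60 and 5.45 in WT and 7.52, 8.40 and 7.01 in p50KO. Npy was at 12.05 and 10.48 on the unstimulated WT macrophage arrays and at 4.48 on the unstimulated p50KO array, yet at 10.44 on the p50KO array given IFNb for 3 h. Ifi202b was at 5.01 and 8.12 on the WT arrays, 9.99 on the p50KO array and 4.98 on the IFNARKO array before stimulation.

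Genes called between p50KO and WT macrophages lay often on chromosome 3, that of the disrupted gene: 8 of 42 (19%) against 456 of 9151 (4.98%), an odds ratio of 4.55 (Fisher's exact p = 0.000943). Of these, 7 lie within 200 protein-coding genes of it: Gstcd (13 genes away, 0.68), Eif4e (23, -1.73), Pla2g12a (31, -0.86), Gbp2b (34, 7.22), Mcoln3 (61, -1.63), Gclm (68, -0.86) and Abcd3 (71, -1.11), with Ctsk (-0.49) 321 genes away. The array series was argued against as the cause, since the excess was there in each series fitted alone: 4 of 15 calls in the LPS and IFNb series (Fisher's exact p = 0.00535) and 44 of 595 in the CpG series (p = 0.00817). A passenger segment of the strain in which the gene was disrupted, linked to it, is a candidate explanation that fits the test. Effects of p50 on these genes stay open, for Gbp2b too. Gbp2b is interferon-inducible, yet it was above background on no WT macrophage array, those given IFNb or LPS among them. Before stimulation it was at 4.3 and 4.31 in WT, 4.38 in IFNARKO and 9.09 in p50KO. Its difference therefore cannot be read as a stronger form of an interferon response seen in WT.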
